A study of Mus musculus with 3 samples.

How the data were processed

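Polyadenylated RNA of Min6 cells, a mouse insulinoma line used as a model of the pancreatic beta cell, was sequenced in 3 libraries. The 3 groups were low glucose (LG), high glucose (HG), and low glucose with GlcNAcstatin (LG+GNS), with 1 library in each. GlcNAcstatin inhibits O-GlcNAcase, the enzyme that removes O-linked N-acetylglucosamine (O-GlcNAc) from proteins, so that the modification builds up. Per the labels' protocols, cells of passages 20 to 30 grown in medium with 4.5 mM glucose were held in their condition for 6 h. They were then moved through medium with 0.5 mM glucose and returned to their condition for 1 h. The labels used here give no glucose concentration for LG or HG and no dose of GlcNAcstatin. RNA with an integrity number of at least 9.5 entered at 500 ng, libraries were amplified for 10 PCR cycles, and sequencing was paired-end on an Illumina HiSeq instrument, per the labels' protocols. The labels do not say whether the libraries kept the strand, so reads of overlapping genes on opposite strands may not have been told apart.

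The authors deposited 1 table of log2 normalized expression values with 1 column per library and 22850 gene rows. Of these rows 22369 were protein-coding genes and 481 were immunoglobulin segments, and no mitochondrially encoded gene was among them. Per the submitters' processing notes, FastQC, TopHat 1.4 and SAMtools were used. The same notes list the human builds hg19 and GRCh37, although the gene identifiers and symbols in the table are mouse. The mouse assembly, the annotation version, the counting tool and the normalization method are not given in the sources used here. Of 21021 identifiers shared with a GENCODE annotation of GRCm38, only 282 had the same start, and the last gene on chromosome 7 ended at 152509964 in the table against 145324086 in that annotation. Positions are therefore given as the table lists them, on an unnamed mouse assembly that is not GRCm38.

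Back-transformed values summed to 30700000 in LG, 31100000 in HG and 30900000 in LG+GNS, rounded. Low back-transformed values clustered at multiples of a step in each library, 2.03 in LG, 2.02 in HG and 1.88 in LG+GNS, held by 628, 666 and 697 genes. The deposited log2 values were therefore read as library-scaled read counts in which 1 read pair counts as about 2 reads. This reading puts the depth at about 15100000, 15400000 and 16500000 read pairs assigned to genes. With a tolerance of 0.02 reads, only 52.7%, 52.3% and 54.8% of the values under 60 were whole numbers of reads. Whole reads could thus not be recovered, and no count model was run. In LG 7260 genes, in HG 7223 and in LG+GNS 7215 were listed at 0, which back-transforms to 1, so a listed 0 may stand for a value of 1 or less.

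From the deposited values, back-transformed values were summed per gene symbol where rows of a symbol had different positions (118 symbols), which gave 22721 symbols. Fold changes are differences of log2(normalized count + 1), a scale that understates changes of low genes. Genes with a mean of at least 50 normalized counts over the 3 libraries, 11974 symbols, were kept. The design written before the data were examined named a minimum of 50 for counts and of 1 for back-transformed log2 values. Since the log2 values held normalized counts and the lowest possible value was 1, the second minimum would have removed no gene. The minimum of 50 was therefore chosen after the unit was known, and the counts of genes without a minimum are given beside the main ones.

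With 1 library per group there was no test between conditions. Counts of genes past 2-fold describe these libraries. Intervals in the report are approximate 95% intervals for counting error, from the number of read pairs inferred above. They hold neither the spread between cultures nor that from amplification, and reads without molecular identifiers are not independent molecules. Counting error alone was simulated 100 times as 3 libraries with the same expected value per gene. For genes past 2-fold in HG a second simulation, added after the data were seen, gave LG and LG+GNS the mean of both values and HG its own value, 100 times. In simulated data of 11978 genes for HG against LG, true 4-fold and 3-fold changes were past 2-fold for 100% of the genes, true 1.5-fold changes for 0%, and unchanged genes for 0.017%.

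Before the data were examined, 25 gene lists, the alternatives to each choice and the rule for named genes were fixed. The lists covered the insulin and secretory granule, beta cell transcription factors, immediate early genes, glucose-responsive genes and targets of ChREBP, and the O-GlcNAc and hexosamine pathway. Others covered glycolysis, stimulus-secretion coupling, endoplasmic reticulum chaperones, ATF4 and the integrated stress response, sterol synthesis, heat shock proteins, NRF2 targets, hypoxia targets and chromatin regulators tied to O-GlcNAc. Further lists held nuclear oxidative phosphorylation genes, mitochondrially encoded RNA, ribosomal proteins, ribosome biogenesis, S phase and mitosis, replication-dependent histones, and long nuclear and intron-retaining RNAs. The last lists held other islet endocrine cells, acinar and ductal cells, fibroblast, endothelial and immune cells, and housekeeping genes. Another 5 lists were added after the data were seen. They held cytosolic and mitochondrial aminoacyl-tRNA synthetases, feedback genes of the ERK pathway, COPII and COPI transport, and KRAB zinc finger genes. For each list the median log2 fold, the number of genes past 1.5-fold and the percentile of the median among 10000 random lists of the same size, matched on mean expression in 20 bins, were computed. The percentile describes these libraries and is no test of the conditions.

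The genes named were the 12 with the largest log2 fold each way for HG and for LG+GNS against LG and the 5 largest each way for HG against LG+GNS. Gene models, predicted genes and clone names, microRNA and small nucleolar RNA genes, and olfactory and immunoglobulin genes were counted but not named. Ins1, Ins2, Ogt, Oga (listed under its older symbol Mgea5) and Txnip were always named, as were up to 4 genes of each list with the largest absolute fold in either comparison. Any other gene is said to have been chosen after its values were seen. Alternatives were pseudocounts of 0.1 and 5, no minimum, a minimum of 5, rescaling by median of ratios or to the same upper quartile, the highest row per symbol, a 1.5-fold threshold and unmatched random lists, with 2000 lists. A minimum of 250, the deposited log2 values without a pseudocount, leaving out Myo1h, and removing trends on GC content, length and mean from list medians were added after the data were seen. These trends on GC content, length and mean were removed as medians of 40 bins each, with 2000 matched random lists for the percentiles and GC content and length of the longest coding transcript in the GENCODE annotation for 11654 of the 11974 genes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.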

Results

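Transcript levels were measured in Min6 cells kept in low glucose, in high glucose, or in low glucose with the O-GlcNAcase inhibitor GlcNAcstatin. Cells spent 6 h in their condition, passed through 0.5 mM glucose and returned to the condition for 1 h. Each condition had 1 library, so no difference between conditions has a replicate check or a p-value. The 3 libraries held between 30700000 and 31100000 normalized read counts, and about 15100000 to 16500000 inferred read pairs. In each of the 3 libraries the genes with the most normalized read counts were Chga, Ins2 and Scg2, all of them encoding secretory granule proteins. Read counts grow with transcript length, so this order is not one of transcript numbers. The top 10 genes held 4.42% to 4.57% of the counts. Of 15 marker genes of fibroblast, endothelial and immune cells, 0 reached a mean of 50 normalized counts. The acinar and ductal list had 5 genes above that minimum, among them Krt7 and Spp1, and 8 genes of other islet endocrine cells were above it, among them the hormone genes Gcg, Ppy and Sst at means of 7692, 579 and 212. In the series the conditions were set up to ask whether O-GlcNAc links glucose to gene regulation in beta cells, the insulin genes in particular.

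High glucose was compared with low glucose to describe how transcripts differed between the glucose levels after these 6 h and 1 h steps. Transcripts of the ATF4 and integrated stress response, which amino acid shortage and endoplasmic reticulum stress induce, were lower in HG in all 21 measured genes. Of 31 measured immediate early genes 23 were higher, such as Sik1 and Nr4a1, as was the glucose-responsive gene Txnip. The insulin transcripts Ins1 and Ins2 differed by only 0.03 and 0.00 on the log2 scale. In total 35 genes were at least 2-fold higher and 87 at least 2-fold lower, among 11974 genes. Counting error alone gave 1.84 higher and 1.70 lower genes on average in simulation, and at most 6 and 7. Without the minimum on expression the numbers were 462 and 596, most of them at very low counts.

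All 21 genes of the ATF4 and integrated stress response list were at least 1.5-fold lower in HG, and 14 of them were at least 2-fold lower. The list's median log2 fold was −1.37, at percentile 0 among random lists. Nupr1, a stress-induced chromatin protein, stood at 1086 normalized counts in LG and 141 in HG (log2 fold −2.94, counting interval −3.30 to −2.58). Trib3, a pseudokinase induced by ATF4 (chromosome 2, 152163158 to 152169768, minus strand), was listed at 5997 in LG and 1036 in HG, a log2 fold of −2.53 (interval −2.67 to −2.40). Ddit3, which encodes the transcription factor CHOP (chromosome 10, 126727830 to 126733344, plus strand), was listed at 5769 and 1065, a log2 fold of −2.44 (interval −2.57 to −2.30). Cebpb differed by −1.81. Among genes chosen after their values were seen, Atf4 itself differed by −1.09 and Asns, the asparagine synthetase gene, by −0.88.

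**Figure D1:**
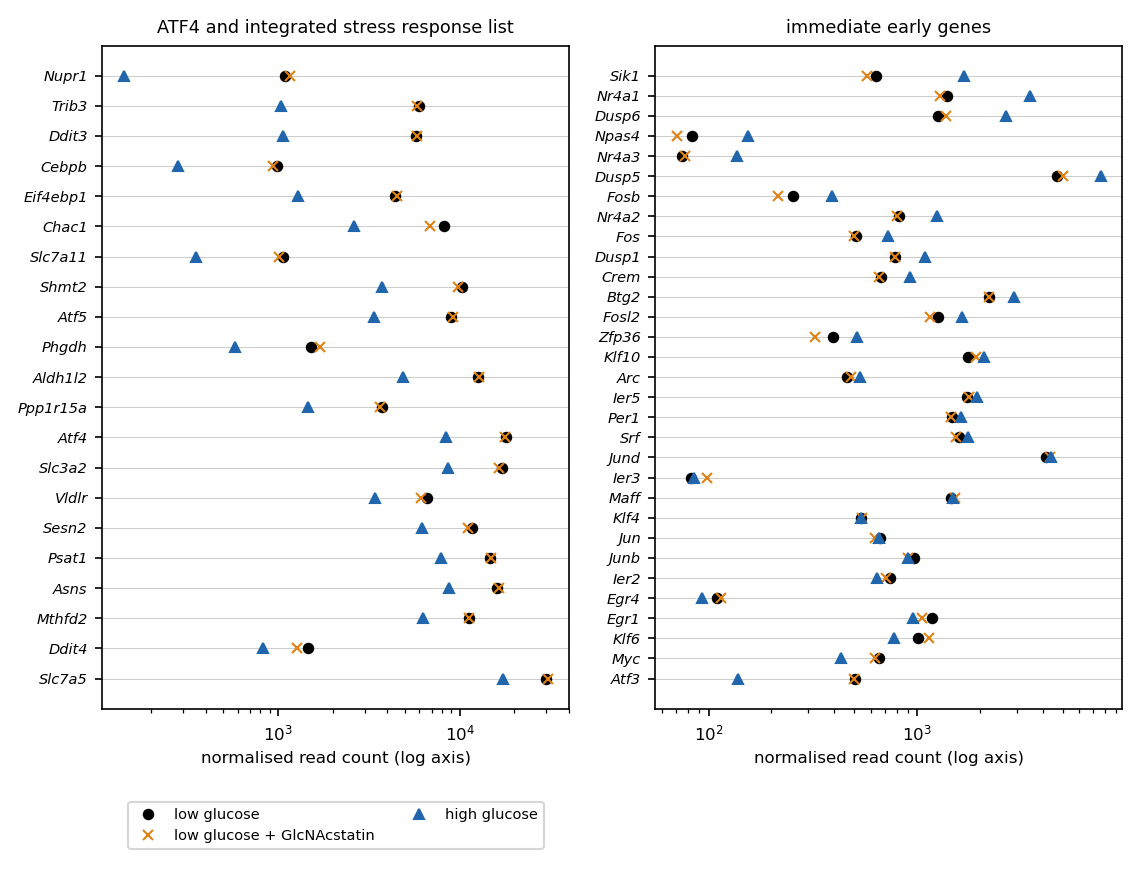
Normalised read counts on a log axis, 1 point per library, for the 21 genes of the ATF4 and integrated stress response list (left) and for all 31 measured immediate early genes (right). In the left panel the HG points lie below the LG points for 21 of 21 genes, while the LG+GNS points lie close to the LG points, with differences of −0.27 to 0.16 on the log2 scale. In the right panel the HG points lie below the LG points for 8 of 31 genes.

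Endoplasmic reticulum chaperones and related genes were also lower in HG, by less. Of 21 measured genes 18 had a negative log2 fold, 2 of them past 1.5-fold, and the median was −0.17 at percentile 0. Herpud1, which acts in the degradation of misfolded proteins, was lower by a log2 fold of −1.15. Sel1l, part of the same degradation machinery, differed by −0.79, the disulfide isomerase gene Pdia4 by −0.51 and the chaperone gene Calr by −0.50. The NRF2 target list had a median of 0.03, with Hmox1 at −0.89 past 1.5-fold and Sqstm1 at −0.55, while Nqo1 was at 0.35. The hypoxia list had a median of −0.12 at percentile 6.68. Adm, which encodes adrenomedullin, differed by −0.93 at 81.1 and 42.2 normalized counts, and Ndrg1 by −0.42.

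Immediate early genes, which are transcribed within minutes of a stimulus, were higher in HG as a group. Of 31 measured genes, 23 were above 0 and 8 below. Past 1.5-fold, 8 were higher and 2 lower, and the median was 0.21 at percentile 100. Sik1, a kinase gene induced by cyclic AMP, was at 637 in LG and 1684 in HG (2.64-fold higher, with a counting interval of 1.21 to 1.59 on the log2 scale). Nr4a1, an orphan nuclear receptor gene (chromosome 15, 101097277 to 101105223, plus strand), was at 1394 and 3494 (log2 fold 1.33, interval 1.20 to 1.45). Dusp6, which encodes an ERK phosphatase, differed by 1.08. The 2 genes at least 1.5-fold lower were Atf3 at −1.84, which is also a known target of ATF4, and Myc at −0.60. Among the others below 0 were Klf6 at −0.39, Egr1 at −0.31 and Jun at −0.02. These 3 genes and Myc were chosen after their values were seen. In the glucose-responsive list 2 of 20 genes were at least 1.5-fold higher, the G protein regulator gene Rgs16 at 1.12 and Txnip at 0.84. The median of that list was 0.12 at percentile 99.0, or 97.2 once trends on GC content, length and mean were removed. Txnip, a thioredoxin-binding protein gene and a known target of the glucose sensor ChREBP, was at 2145 in LG and 3835 in HG (interval 0.73 to 0.95), while Khk was at −0.33.

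Beta cell transcription factors had a median of 0.16 at percentile 99.7, with 15 of 20 genes above 0 and 0 past 1.5-fold. Glis3 differed by 0.45, Ucn3, a beta cell hormone gene kept in that list, by 0.31, Pdx1 by 0.31 and Mnx1 by 0.29. The insulin and secretory granule list had 0 of 20 genes past 1.5-fold and a median of 0.06 at percentile 47.3. That median turned to −0.02, with 11 of 20 genes below 0, once trends on GC content, length and mean were removed. Ins2 (chromosome 7, 149864561 to 149885415, minus strand) was at 200320 normalized counts in LG and 200410 in HG, with a counting interval of −0.01 to 0.01. Ins1 (chromosome 19, 52338813 to 52339946, plus strand) was at 58541 and 59971, with an interval of 0.01 to 0.06. Ins1 and Ins2 are close paralogs, so the share of reads given to each is uncertain. Pcsk1, the prohormone convertase gene, differed by 0.36 and the granule protein gene Vgf by 0.34.

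In the O-GlcNAc and hexosamine list 0 of 15 genes were past 1.5-fold, and the median was −0.05 at percentile 14.4, or −0.11 at percentile 2.30 once trends on GC content, length and mean were removed. Pgm3 and Gfpt1, which encode enzymes that make the sugar donor for O-GlcNAc, differed by 0.54 and 0.39, and Uap1l1 and Amdhd2 by −0.47 and −0.41. Ogt, the O-GlcNAc transferase gene, differed by −0.20 (interval −0.29 to −0.11), and Oga by 0.14 (interval 0.04 to 0.25). In the chromatin regulator list 0 of 24 genes were past 1.5-fold, with Tet1 at 0.38, Mll2 at 0.36 and Yy1 at −0.22, and the median of −0.00 took the opposite sign under both rescalings. The glycolysis list had a median of 0.04, stimulus-secretion coupling 0.05 and sterol synthesis −0.03, each with 0 genes past 1.5-fold, and the stimulus-secretion median turned to −0.01 once the same trends were removed. Within these lists Eno1 was at 0.30, the incretin receptor gene Gipr at −0.47, Ffar1 at 0.27 and Mvd at −0.55.

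Nuclear genes of oxidative phosphorylation had a median of 0.10 at percentile 97.8, with 24 of 25 above 0, Ndufa4 at 0.32 and Uqcrh at 0.31. Once trends on GC content, length and mean were removed, a step chosen after the data were seen, that median was 0.05 at percentile 90.5 with 21 of 25 above 0. Heat shock protein genes had a median of 0.11, with the co-chaperone gene Bag3 at 0.89. In the S phase and mitosis list 1 of 25 genes, the cyclin gene Ccnd2 at 0.93, was past 1.5-fold, and the median was 0.06. Ribosome biogenesis genes had a median of 0.07, with Cad at 0.44. Ribosomal protein genes had a median of −0.07 at percentile 2.09, or 4.70 among unmatched lists, with 25 of 32 below 0, Rpl22 at −0.32 and Rpl5 at 0.43. The 3 measured replication-dependent histone genes had a median of 0.41, with Hist1h1d at 0.67. Intron-retaining genes had a median of −0.07 at percentile 5.22, with Clk1 at −0.36 and Srsf7 at 0.27. Housekeeping genes had a median of 0.08, with Actb at 0.27 and Ppia at −0.60. Ppia and the ribosomal protein genes have processed pseudogenes, so their values are uncertain. Among markers of other cells the acinar and ductal list had a median of 0.19 at percentile 98.1, or 97.0 among unmatched lists and 96.8 with the trends removed, with Spp1 at 0.39, and the other islet list −0.01, with Sst at −0.34.

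Outside the lists, B3gnt2, a glycosyltransferase gene (chromosome 11, 22734747 to 22760961, minus strand), had the highest log2 fold of the named genes, 2.51, at 52.5 normalized counts in LG and 304 in HG (interval 1.91 to 3.11). Myof, Flrt3, Baalc, Epha2, Prr5l, Arhgap8, Capn6, Mfsd2a and Nfkbid followed at 1.64 to 1.15, each at fewer than 90 normalized counts in LG, together with Sik1 and Nr4a1. The lowest named genes were led by Slc1a7, a glutamate transporter gene, at −3.82 with 98.5 counts in LG and 6.05 in HG (interval −5.50 to −2.14). Nupr1, Extl1 at −2.89, Trib3, Ddit3, Adm2 at −2.41, Trim66 at −2.32, the glycine transporter gene Slc6a9 at −2.01, Fut1 at −1.86 and Atf3 followed. Rpl17 differed by −2.20 and is reported as uncertain, since the GENCODE annotation names 11 pseudogene copies of it. Myo1h was at 236 in LG, was listed at 0 in HG and was at 2.51 in LG+GNS, so no fold is given.

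Low glucose with GlcNAcstatin was compared with low glucose alone to describe how transcripts differed with the inhibitor and without added glucose. The data used here hold no measure of O-GlcNAc, so whether it built up in this culture cannot be told. The stress response, immediate early and insulin gene lists had medians within 0.02 log2 of their low-glucose levels. Only 4 genes were at least 2-fold higher and 7 at least 2-fold lower, where counting error alone gave 1.49 and 1.56 on average and at most 4 and 5. At 1.5-fold the numbers were 43 and 45, against 35.6 and 34.7 from counting error alone. Without the minimum on expression 457 and 396 genes were past 2-fold.

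Ins1 was at 56285 in LG+GNS, a log2 fold of −0.06 (interval −0.08 to −0.03), and Ins2 at 195150, a log2 fold of −0.04 (interval −0.05 to −0.03). The ATF4 and integrated stress response list had 0 of 21 genes past 1.5-fold and a median of −0.02 at percentile 1.44, or 15.3 among unmatched lists and 4.22 with the trends removed, with Trib3 at −0.05, Ddit3 at 0.01 and Nupr1 at 0.11. The immediate early list had 0 of 31 genes past 1.5-fold and a median of −0.02, with Sik1 at −0.15 and Nr4a1 at −0.11. Txnip differed by 0.02 (interval −0.10 to 0.14), and Rgs16 by 0.37. The O-GlcNAc and hexosamine list had a median of 0.02, with Ogt at −0.21 (interval −0.30 to −0.12), Oga at 0.10 (interval −0.01 to 0.21) and Pgm3 at 0.17. Ogt differed by 0.01 (interval −0.08 to 0.10) between HG and LG+GNS.

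The list that stood lowest was that of intron-retaining genes, whose transcripts are known to be kept in part in the nucleus with introns unspliced. The deposited values are totals per gene, so neither intron retention nor nuclear RNA was measured. All 10 measured genes of that list were lower in LG+GNS, none past 1.5-fold, and the median was −0.14 at percentile 0. Clk1, a kinase gene for splicing factors, differed by −0.30 (interval −0.41 to −0.19), Clk4 by −0.16, Rbm39 by −0.12 and Srsf7 by −0.10. Ogt, at −0.21, was also in that list. Directly between HG and LG+GNS the list had a median of 0.01 at percentile 53.0, with 6 of 10 genes above 0. The difference of this list may thus rest in part on the shared LG library. The other members of that list, such as Malat1, were not analysed here, since the rows of the table are protein-coding genes and immunoglobulin segments. The stimulus-secretion list had a median of −0.03 at percentile 0.24, or 6.20 among random lists not matched on expression, with Gipr at −0.34 (interval −0.52 to −0.15), a gene that differed by −0.14 (interval −0.33 to 0.06) between HG and LG+GNS. Endoplasmic reticulum chaperones had a median of 0.05 at percentile 99.3, or 96.1 among unmatched lists, with 20 of 21 genes above 0 and Pdia4 at 0.07. With the trends removed 14 of 21 were above 0 and the median was 0.02. The medians of the other lists fixed before the data were seen lay between −0.03 and 0.04, with Hspa1b at 0.37, Rpl5 at 0.38, Rps23 at −0.50, Peg10 at −0.49, Khk at −0.28 and Ezh1 at −0.22 among their members. Khk differed by −0.05 between HG and LG+GNS.

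**Figure D2:**
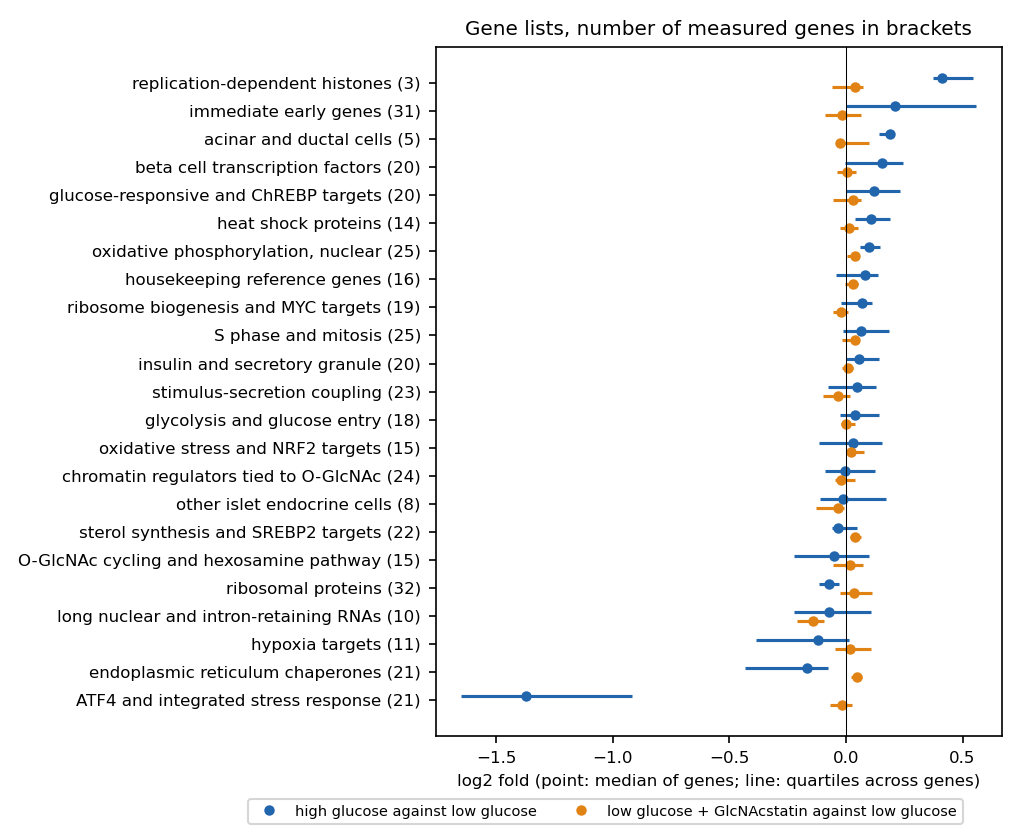
Median log2 fold of each gene list (points) with the quartiles across its genes (lines), for high glucose (blue) and low glucose with GlcNAcstatin (orange), each against low glucose and with 1 library per condition. The ATF4 and integrated stress response list stands at −1.37 in high glucose and at −0.02 with GlcNAcstatin.

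The named genes that were higher in LG+GNS were all at low counts, fewer than 80 in LG. Baalc was at 34.5 in LG and 72.2 in LG+GNS (log2 fold 1.05, interval 0.22 to 1.87), and the apoptosis gene Bik was at 1.01. Garnl3, Lzts1, Wdr17, Ngb, Wipf3, Pkhd1, Sema6c, Nhlrc1, Nfkbid and Amd-ps3 followed at 0.88 to 0.75. Among the lower genes Rpl23a was at 970 in LG and 167 in LG+GNS, a log2 fold of −2.53 (interval −2.86 to −2.20), and is reported as uncertain because of 14 named pseudogene copies. Lrrc14b at −1.66, Dbndd2 at −1.65, Sla2 at −1.15, Il18bp at −1.14 and Rgs11 at −0.90 followed, and then Trim36, Prdm1, Npr1, the DNA damage gene Ddb2 and the ubiquitin ligase gene Park2 at −0.86 to −0.82. Of the 12 named genes each way, the interval for HG against LG+GNS held 0 for 8 higher and 7 lower genes, among them Npr1, Ddb2 and Park2, which were also lower in HG by −1.04, −0.59 and −0.80. The differences of these genes, and those of Ogt, Khk and Gipr, may thus rest on the shared LG library. Myo1h, at 236 in LG and 2.51 in LG+GNS, about 1 read pair, was the lowest gene, and no fold is given because it was near 0 in HG as well.

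High glucose and GlcNAcstatin were then set side by side, to ask whether genes that differed with glucose also differed with the inhibitor. Of the genes with a mean of at least 250 normalized counts, 45 were at least 2-fold lower in HG with a median of −1.36, and the same genes had a median of −0.02 in LG+GNS. The 7 genes at least 2-fold higher in HG had a median of 1.11, and of 0.05 in LG+GNS. Over these 52 genes the median difference in LG+GNS, counted in the direction of HG, was 0.02 with quartiles of −0.03 and 0.07, and 33 of 52 had the same direction, with 0 past 1.5-fold in LG+GNS. Simulation with LG and LG+GNS at the same expected value gave a median of 0.01 for such genes and 54.8% in the same direction, from the shared LG library alone. The minimum of 250 was chosen after the data were seen. With the minimum of 50 the 35 higher genes had a median of 0.34 in LG+GNS, 26 of them in the same direction and 8 past 1.5-fold, among them Baalc at 1.05 and Nfkbid at 0.76. The 87 lower genes had a median of −0.04, 56 in the same direction and 3 past 1.5-fold, Myo1h among them. With the minimum of 50 the same simulation gave a median of 0.19 for higher genes, and of 0.02 to 0.37 over the draws, with 74.6% in the same direction and 14.9% past 1.5-fold, against 74.3% and 22.9% of the 35 genes. For lower genes it gave −0.03, 58.8% and 2.63%, against 64.4% and 3.45% of the 87 genes.

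**Figure D3:**
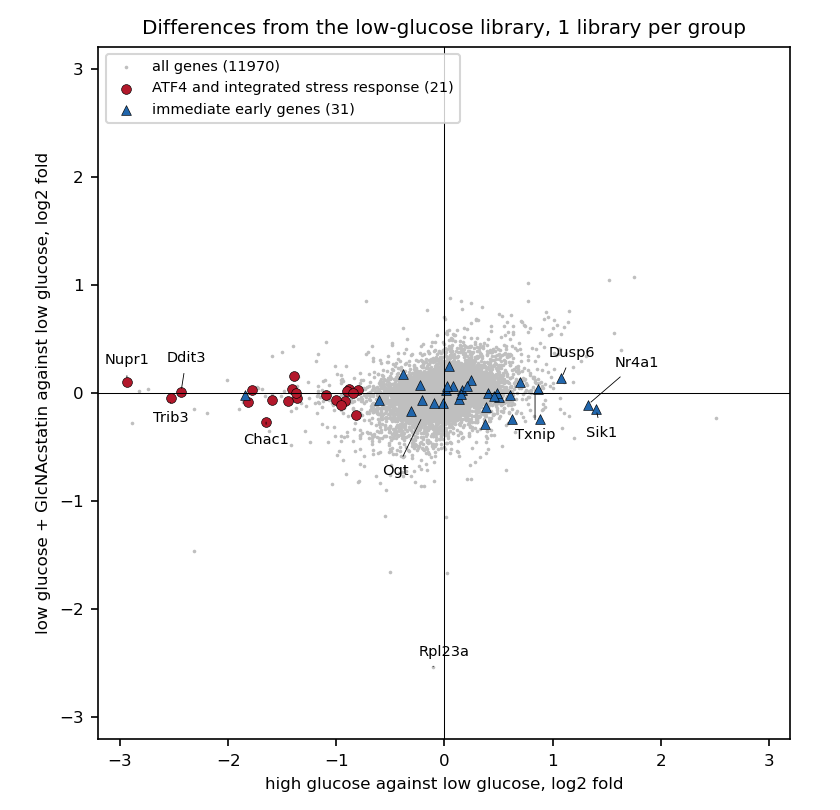
Log2 fold of high glucose (horizontal axis) and of low glucose with GlcNAcstatin (vertical axis) against the same low-glucose library, 1 point per gene, for 11970 genes. Another 4 genes lie outside the axes, and immediate early genes are blue. Genes of the ATF4 and integrated stress response list (red) spread from −2.94 to −0.80 along the horizontal axis and from −0.27 to 0.16 along the vertical axis.

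Across the 11974 genes the log2 folds of HG and of LG+GNS had a Pearson correlation of 0.32 and a Spearman correlation of 0.30. Both used the same LG library, which gives a positive value with no effect, and in simulated unchanged libraries the Pearson correlation was 0.51. HG was unchanged in that simulation, with an interquartile range of 0.107 against 0.261 here. A wider HG spread lowers the correlation, so 0.32 cannot be read as less alike than unchanged libraries. The covariance was 0.0156, against 0.00921 in simulation with counting error and 0.0102 with error as wide as the LG+GNS difference. Without Myo1h the covariance was 0.0121 and the Pearson correlation 0.27. With a mean of at least 250 the covariance was 0.00626, against 0.00409 and 0.00520. Genes are not independent replicates, and the single LG library could not be split, so part or all of any excess may come from that library. At 1.5-fold, 21 genes were higher in both, where independent lists would share 0.722 and simulated unchanged libraries shared 11.4. For lower genes the overlap was 11, against 1.15 and 5.64. In those simulated libraries only 38.29 higher and 37.75 lower genes were past 1.5-fold in HG, against 201 and 307 here. This overlap was not simulated with HG at its own value, so no excess can be read from it. With a mean of at least 250, 0 genes were past 1.5-fold in the same direction in both. LG+GNS then had only 0 higher and 3 lower genes past 1.5-fold, and independent lists would share 0.046 lower genes. This 0 thus cannot show whether the differences overlap.

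Compared directly with LG+GNS, HG had 29 genes at least 2-fold higher and 81 at least 2-fold lower, or 458 and 610 without the minimum on expression. B3gnt2 at 2.74, Rpl23a at 2.43, Lrrc14b at 1.69, Sik1 at 1.55 and Nr4a1 at 1.43 were the highest named genes. Slc1a7 at −4.29, Nupr1 at −3.04, Extl1 at −2.61, Trib3 at −2.48 and Ddit3 at −2.44 were the lowest. All 21 genes of the ATF4 and integrated stress response list were again at least 1.5-fold lower in HG, with a median of −1.38, and the immediate early list had a median of 0.16. The interquartile range of log2 folds over all genes was 0.261 for HG against LG and 0.134 for LG+GNS against LG, where counting error alone gave 0.107 and 0.106.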

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

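The minimum of 250, the values without a pseudocount, the run without Myo1h and the removal of trends on GC content, length and mean were chosen after the results were seen. Each log2 fold of a named gene was checked once per alternative that applied to it. Of these checks 2657 stayed within the counting interval, and 1 moved, Glis3 in HG at 0.57 with the highest row per symbol. A changed minimum or leaving out Myo1h cannot alter the fold of a gene. Those checks, 266 per minimum and 264 without Myo1h, were thus the same by construction. Of the checks of list medians 497 stayed within their range. Without a minimum the acinar and ductal median in HG was 0, because most added genes were listed at 0, and the histone median in HG was 0.31, for a reason that was not tested. Unmatched random lists put the stimulus-secretion list with GlcNAcstatin at percentile 6.20, the chaperones at 96.1 and the stress response list at 15.3, and in HG the ribosomal proteins at 4.70 and the acinar and ductal list at 97.0.

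With the trends removed the insulin and granule median in HG turned to −0.022, and with GlcNAcstatin it was −0.019 at percentile 2.30. In HG the oxidative phosphorylation median was 0.048 at percentile 90.5 and the ribosome biogenesis median 0.10 at percentile 98.7. Percentiles in HG were 97.2 for glucose-responsive genes, 2.30 for the O-GlcNAc list and 96.8 for the acinar and ductal list. With GlcNAcstatin the medians were 0.022 for the chaperones, 0.0027 for NRF2 targets and 0.0087 for oxidative phosphorylation, and the percentiles 4.22 for the stress response and 98.5 for sterol synthesis. Across 11654 genes the log2 fold with GlcNAcstatin had Spearman correlations of −0.20 with GC content, 0.01 with length and 0.05 with the mean. In HG these were −0.08, 0.09 and 0.11. The trends were removed together, so which of them acted on each list was not tested.

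Counts of genes followed the minimum and the threshold. With no minimum, 462 genes were higher and 596 lower in HG than LG, 457 and 396 in LG+GNS than LG, and 458 and 610 in HG than LG+GNS. With a mean of at least 5 these were 232 and 346, 198 and 175, and 222 and 345. With a mean of at least 250 they were 7 and 45, 0 and 2, and 7 and 48. At 1.5-fold they were 201 and 307, 43 and 45, and 195 and 284. With a pseudocount of 5, 1 gene was higher in LG+GNS than LG. The correlation of both differences was 0.44 with no minimum, 0.40 with a mean of at least 5, 0.24 with at least 250 and 0.27 without Myo1h. Low genes carry the most counting error, and the cause of each change was not tested further. Rescaling moved each library by less than 0.4%, with factors of 0.996 to 1.003. No paired analysis was possible because each group had 1 library.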

Other observations

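The lists of tRNA synthetases, ERK feedback, COPII and COPI transport and KRAB zinc finger genes were chosen after the results were seen. So were the tests of scaling, of the tRNA synthetases and of the gap between the intron-retaining list and other splicing factor genes. Genes named here were chosen after their values were seen. COPII and COPI genes, which carry proteins between the endoplasmic reticulum and the Golgi, had log2 folds above 0 in HG in 20 of 20 cases, of which 1 was past 1.5-fold, with a median of 0.30 at percentile 100. The gene past 1.5-fold was Kdelr3, a retrieval receptor gene, at 0.93, and Sec13 was at 0.52 and Sec24d at 0.45. With GlcNAcstatin the COPII and COPI median was 0.01.

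Feedback genes of the ERK pathway had a median of 0.43 in HG at percentile 100, with 5 of 12 genes at least 1.5-fold higher. Dusp6 was at 1.08, Spry4 at 1.00, Etv4 at 0.71 and Etv5 at 0.68. With GlcNAcstatin their median was 0.01. KRAB zinc finger genes had a median of −0.03 in HG and −0.02 with GlcNAcstatin, and mitochondrial tRNA synthetases had −0.10 and −0.04.

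The lower stress response transcripts in HG may reflect lower ATF4 activity at the higher glucose level, as a hypothesis from these libraries. A scaling difference would shift all genes alike, and the list lay −1.37 from the median of all genes. Removing trends on GC content, length and mean left the list at −1.34, which argues against those as the whole cause. Cytosolic tRNA synthetases, other known targets of ATF4, had a median of −0.41 with 6 of 20 genes at least 1.5-fold lower, such as Sars at −0.86 and Aars at −0.74, while 6 of 20 were above 0, such as Kars at 0.14, so not all of them were lower. In LG+GNS, the other low-glucose library, the list had a median of −0.02 against LG. Against LG+GNS it had a median of −1.38 in HG, with 21 of 21 genes at least 1.5-fold lower. The difference was thus not particular to the LG library. A difference other than glucose between the HG culture and the low-glucose cultures stays open, because there was 1 library per group.

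The lower totals of intron-retaining genes with GlcNAcstatin may reflect the inhibitor, as a hypothesis, but the design leaves this open. Retention of introns was not measured. Removing trends on GC content, length and mean left 10 of 10 genes below 0 at percentile 0 and a median of −0.18, which argues against those trends. The list held Ogt, which encodes no splicing factor, at −0.21. Among 65 splicing factor genes outside the list 39 were below 0, with a median of −0.01 at percentile 0.22. Trends on GC content, length and mean were not removed for these genes, and HG was not compared with LG+GNS for them. A small shift of splicing factor transcripts in general thus stays open. The intron-retaining genes lay −0.13 from the median of those genes. A difference between the LG and LG+GNS cultures other than GlcNAcstatin stays open with 1 library per group, as does a high value of the shared LG library, since 7 of 10 genes, such as Clk1 at −0.36 and Rbm39 at −0.33, were lower in HG too, although Srsf7 at 0.27, Tia1 at 0.15 and Srsf6 at 0.15 were higher, and the median of HG against LG+GNS was 0.01 at percentile 53.0.

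Ribosomal protein genes, whose proteins cells make in similar amounts, were listed at very different levels, from a log2 mean of 3.97 for Rps27 to 14.2 for Rpl8 over 76 genes. Read counts also grow with transcript length, which was not accounted for here. Reads shared with processed pseudogenes may lower the listed values. Across these genes, which are not independent replicates, the number of named pseudogene copies and the level had a Spearman correlation of −0.46 (permutation p = 4e-05) and a Pearson correlation of −0.33. The 58 genes with a named copy had a median of 9.50 and the others of 11.2, and Gapdh, with 2 named copies, was at only 48.9 normalized counts in LG. Only pseudogenes whose symbol was that of the gene followed by -ps were counted, and copies under other names were not. The named copies alone do not account for the whole range. Rps27 had only 1 named copy, Rps28 at 6.45 and Rpl37 at 7.81 had 0, and Rpl31 with 24 was at 9.24. Whether all copies would account for it cannot be told from this count, and no biological explanation was tested.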
